A study of Homo sapiens with 9 samples.

How the data were processed

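RNA was measured in U87MG cells that received 1 of 3 siRNA pools for 48 h and then spent 24 h at 1% oxygen. Each culture was separated by ribosome density into free and monosomal (M), oligosomal (O) and polysomal (P) RNA, and each of the 9 pools gave 1 stranded mRNA library. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned to GRCh38 with STAR 2.5.0, assembled and quantified with Cufflinks 2.2.1 and normalised with Cuffnorm. The deposited values are FPKM, made by the authors for each library and locus. The Cuffnorm option and the annotation release are not given in the sources used here. Every log2 value was computed here from the deposited FPKM.

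The table has 10951 loci, each with at least 1 library near or above 3.001 FPKM, so loci low in all libraries had been left out before deposit. Of these, 413 have no gene name, 1693 join several names and 154 carry a symbol found on more than 1 locus. Of 8845 loci with a single name, 88.5% matched GENCODE release 29 by symbol and place. Gene type and coding length came from that release, and RefSeq patch 14 was used only for other names of genes. Coordinates are 1-based. A small RNA gene lies inside 3787 loci.

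Expression was log2 of the sum of M, O and P plus a pseudocount of 1, and its change the difference between cultures. TE was log2 of P plus 1 over M plus 1. Loci with no name or with a symbol on several loci were left out, as were those with a mean below 1 FPKM over the 9 libraries, which left 10366, of which 8156 hold a single coding gene. A locus counted as risen or fallen in expression when it changed at least 2-fold with the same sign in all 3 fractions. For TE it had to change at least 2-fold with the same sign when O was added to P. With 1 library per group no p-value, standard error between replicates or test across genes was computed. The comparisons, rules, gene lists and most alternatives were set before the data were examined.

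An exact 0 in FPKM can stand for a failed estimate rather than for no RNA. There were 91 such values in siHIF1A P, 137 in siHIF2A P, 22, 24 and 20 in the O libraries of siCTL, siHIF1A and siHIF2A, and none in M or in siCTL P. Genes with such values are called listed at 0 and no fold is given against them. Depth was inferred from loci of 390 bp, whose FPKM fall on multiples of a step, and counting error was computed from it. For coding loci the median counting error was 0.031, 0.032 and 0.031 log2 for expression and 0.083, 0.088 and 0.085 for TE. Libraries of the same fraction correlated at 0.980 or above, and M and P libraries at 0.542 to 0.597.

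The 33 fixed gene lists cover glycolysis, core hypoxia targets, genes preferring HIF-2α, cytosolic and mitochondrial ribosomal proteins, initiation factors, other TOP genes, the respiratory chain, mitochondrially encoded genes and central metabolism. They also cover lipid synthesis, stress responses, tRNA synthetases, replication, mitosis, histones, matrix, receptor tyrosine kinases, interferon, p53 and NF-κB targets, autophagy, RNA-binding regulators, spliceosome, proteasome, long non-coding RNAs, glial markers and 3 lists of other cell types. Members sharing a locus with another coding gene or found on several loci were left out. A list with at least 5 members was summarised by its median and by its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Percentiles below 2.5 or above 97.5 were taken as outside the range. Matching on 8 bins of coding or transcript length within 5 bins of expression was added after the data were seen.

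Genes named always were HIF1A, EPAS1, ARNT, VEGFA, SLC2A1, PGK1, LDHA, CA9, ADM, BNIP3, PDK1, NDRG1, EGLN3, ANKRD37, CCND1, TGFA, EGFR, PDGFRA, EIF4E2 and EIF5B. EGLN3 is not in the table used. In addition the 10 highest and 10 lowest loci past the size rule with a mean of at least 5 FPKM were eligible, and up to 4 members of each list by size of change. Symbols on several loci, joined loci and Y-linked genes were not eligible. Exceptions are HIF1A, SLC2A1, PGK1 and PDGFRA, which sit in joined loci. Some genes that the rule names are not reported here. Other joined loci named as a locus, and the 10 highest and lowest among coding loci without a small RNA gene inside, were chosen after their values were seen, as were genes named for a fuller account of a list.

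Alternatives tried were a pseudocount of 0.1, no filter, a filter of 5 FPKM, rescaling to the same FPKM total, setting the median of all loci to 0, leaving out each fraction, the mean of the 3 log2 differences, other places for O in TE, size alone, a 1.5-fold size and keeping repeated symbols apart. Added after seeing the data were unnamed loci included, coding loci only, coding loci without a small RNA gene, loci listed at 0 left out, single-name list members and removal of the coding length trend in 40 bins. Overlap was checked against simulations of unchanged cultures sharing the control, 20 with all spread as noise and 20 with counting error alone. The method was tested on simulated data with planted changes and counting error only, without any spread between cultures. It recovered none at 1.5-fold, 16.0 to 20.0% of expression and 10.0 to 18.0% of TE changes at 2-fold, and at least 88.0% at 3-fold, with at most 3 of 10136 unchanged loci counted. A planted list shift of 0.3 came back as 0.233 to 0.289. Analyses used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.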

Results

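The series asks how HIF-1α and HIF-2α, the oxygen-regulated subunits of the hypoxia-inducible transcription factors, shape mRNA levels and translation efficiency in hypoxic cells. U87MG cells, an established human glioblastoma line, received a control siRNA pool (siCTL), a pool against HIF1A (siHIF1A) or a pool against EPAS1, the gene for HIF-2α (siHIF2A). After 48 h with siRNA the cells spent 24 h at 1% oxygen. Ribosome density fractionation of each culture gave 3 RNA pools: free and monosomal RNA (M), oligosomal RNA (O) and polysomal RNA (P). Each of the 9 combinations of siRNA and fraction has 1 library, so no value carries a replicate and no test between cultures was possible. All libraries came from hypoxic cells, so every statement concerns siRNA against a HIF subunit under hypoxia. The libraries hold RNA only, so the level of HIF protein is not known from them.

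Expression is the log2 of the FPKM summed over M, O and P, and translation efficiency (TE) is the log2 ratio of P to M. FPKM are relative to each library's own RNA, so the sum is not a true RNA total. The deposited table has 10951 loci, of which 10908 reached a mean of 1 FPKM. After loci with no gene name and repeats of a symbol were left out, 10366 were tested. A locus rose or fell if it changed at least 2-fold with the same sign in all 3 fractions, or for TE with the same sign when O was added to P. Read totals are not given in the sources used here, so depth was estimated from the spacing of FPKM values. For 1 kb of effective transcript length, 1 FPKM stood for about 26, 47.2 and 59.7 fragments in siCTL M, O and P. The same figures were 32.8, 56.7 and 63.8 with siHIF1A and 25, 79.0 and 47.1 with siHIF2A. Counting error alone had a median of 0.03 log2 for expression and at most 0.09 for TE of coding loci. This excludes the spread between cultures, which cannot be estimated here.

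EPAS1 (chromosome 2, 46293667 to 46386703) fell by 1.18 log2 with siHIF2A. Its FPKM in M, O and P were 21.16, 71.18 and 102.1 with siCTL, 20.74, 58.04 and 91.5 with siHIF1A, and 19.78, 25.2 and 40.14 with siHIF2A. HIF1A shares a table locus with its neighbour SNAPC1. That locus read 31.77, 35.7 and 89.46 with siCTL, 29.1, 24.97 and 38.69 with siHIF1A, and 31.96, 33.42 and 87.06 with siHIF2A. Its change with siHIF1A was −0.75 log2, short of the 2-fold rule. EPAS1 and the HIF1A locus were therefore lower in O and P under the siRNA against them and nearly level in M. The level of HIF1A alone cannot be read from the joined locus. ARNT, the shared partner of both subunits, had changes of 0.40 with siHIF1A and −0.01 with siHIF2A.

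**Figure D1:**
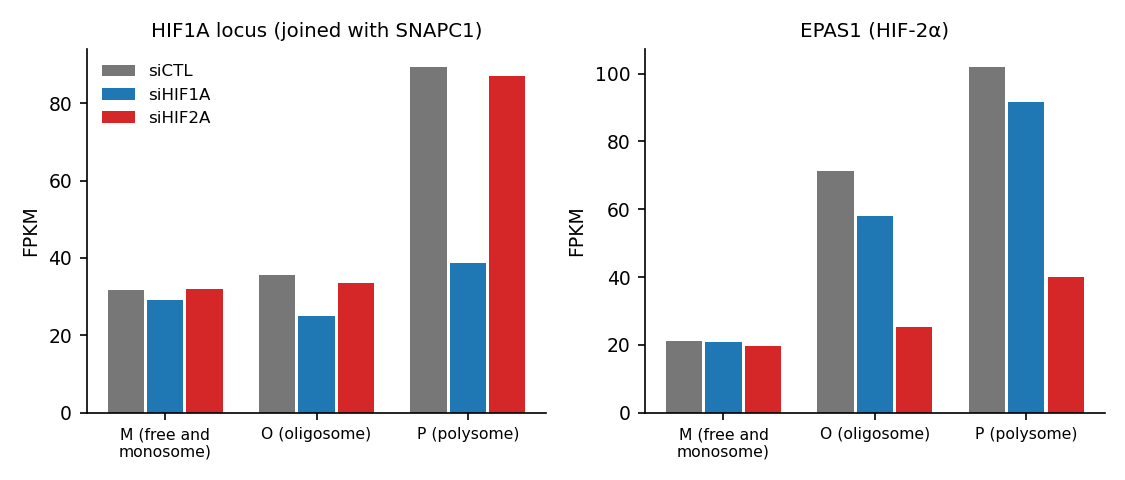
FPKM of EPAS1 and of the locus holding HIF1A and SNAPC1 in each fraction and siRNA culture. Each bar is 1 library.

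With siHIF1A, mRNA of glycolysis and cholesterol synthesis genes was lower. Few single genes crossed the 2-fold line: 20 loci rose and 21 fell, 11 and 13 of them protein-coding, and after rescaling to equal FPKM totals 39 rose and 22 fell. Without O the split was 33 and 24, and without P it was 26 and 33. Among the genes that fell, AKR1B1, the aldose reductase that turns glucose into sorbitol, fell by 1.36. FASN (chromosome 17, 82078333 to 82098332), the fatty acid synthase, fell by 1.10, and the cytidine deaminase CDA by 1.03. IKBKAP, a scaffold of the Elongator complex that modifies tRNA, fell by 1.38. LURAP1L (−1.20), the orphan receptor MRGPRF (−1.12) and the calcium-binding protein S100A4 (−1.03) also fell.

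Among the genes that rose, SPINK1 (chromosome 5, 147824568 to 147831786), a secreted trypsin inhibitor, rose by 1.70, from 8.83 to 31.29 FPKM in M. The metallothionein MT1M rose by 1.04 and RMRP, the RNA of the RNase MRP enzyme, by 1.10. MAGI2 (1.61) and FHIT (1.29) rose too, both very long genes with small RNA genes inside.

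Among gene lists, the 32 core hypoxia targets had a median of −0.16, at percentile 0.09 of 10000 random lists matched on mean expression, with 22 of the 32 lower. That percentile, like the others here, describes these libraries and is not a test. The 17 glycolysis genes had a median of −0.19 (percentile 0.31), with 14 lower. The wider changes in that list were at PFKFB3 (−0.66), which makes the activator of phosphofructokinase, HK1 (−0.48), PKM (−0.46), the SLC16A3 locus (−0.46) and ENO1 (−0.44). LDHA had −0.36 and the core target CA9 −0.39. PGK1, in a locus shared with ATP7A, had −0.23, BNIP3 −0.16, ANKRD37 −0.28, VEGFA −0.02, PDK1 0.02, the SLC2A1 locus −0.01, NDRG1 0.12 and ADM 0.17. Among core targets with a locus of their own the widest changes were at ANKZF1 (−0.79), LOX (0.59) and INSIG2 (−0.49), and 10 of the 32 targets were higher.

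The 16 fatty acid genes had a median of −0.34 (percentile below 0.01) over 9 lower and 7 higher members, led after FASN by ACSL3 (−0.73), FABP3 (−0.63) and LPIN1 (−0.51). The 19 cholesterol genes had −0.20 (percentile 0.20, 16 lower), with STARD4 at −0.35. Aminoacyl-tRNA synthetases were lower as well, with a median of −0.21 (percentile 0.04) and AARS at −0.68. Their median was also −0.21 with siHIF2A, and −0.04 (percentile 28.34) between the siRNAs. Both comparisons use the same siCTL libraries, so a deviating control cannot be told apart from an effect of each siRNA. Proteasome genes, lower with both siRNAs, share that control. Of 28 proteasome genes 27 were lower (median −0.15, percentile 0.47), PSMD1 most (−0.61). In the other direction stood 29 DNA replication genes (0.18, percentile 99.88; CDT1 0.48), 13 p53 targets (0.19, percentile 99.02, or 90.32 from loci of a single name; FAS 0.53), 53 mitochondrial ribosomal proteins (0.07, percentile 99.38, or 96.72 with coding length matched) and 7 histone genes (0.58, percentile 100), most of which lack poly(A) tails. The 9 genes known to prefer HIF-2α had a median of 0.25 (percentile 99.71), which fell to 0.001 once members below 5 FPKM were left out.

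The remaining lists lay inside the range of random lists for expression. Their medians were −0.02 for 69 cytosolic ribosomal proteins, −0.01 for 37 initiation factors, 0.04 for 12 other genes with TOP motifs, −0.06 for 59 respiratory chain genes, −0.10 for the tricarboxylic acid cycle and −0.07 for the pentose phosphate pathway. ATF4 targets had −0.07, endoplasmic reticulum stress genes 0.07, mitosis 0.001, extracellular matrix −0.06, receptor tyrosine kinases 0.07, interferon response 0.08 and NF-κB targets 0.12. Autophagy stood at 0.09, RNA-binding regulators at −0.09, the spliceosome at 0.04, long non-coding RNAs at −0.05 and glial markers at 0.11. Rescaling all libraries to the same FPKM total turned the ribosomal protein (0.01), respiratory chain (0.01), initiation factor (0.08), ATF4 (0.02) and long non-coding RNA (0.15) medians positive and that of mitosis negative (−0.06, percentile 1.66), and took RNA-binding regulators outside the range (−0.10, 0.43).

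**Figure D2:**
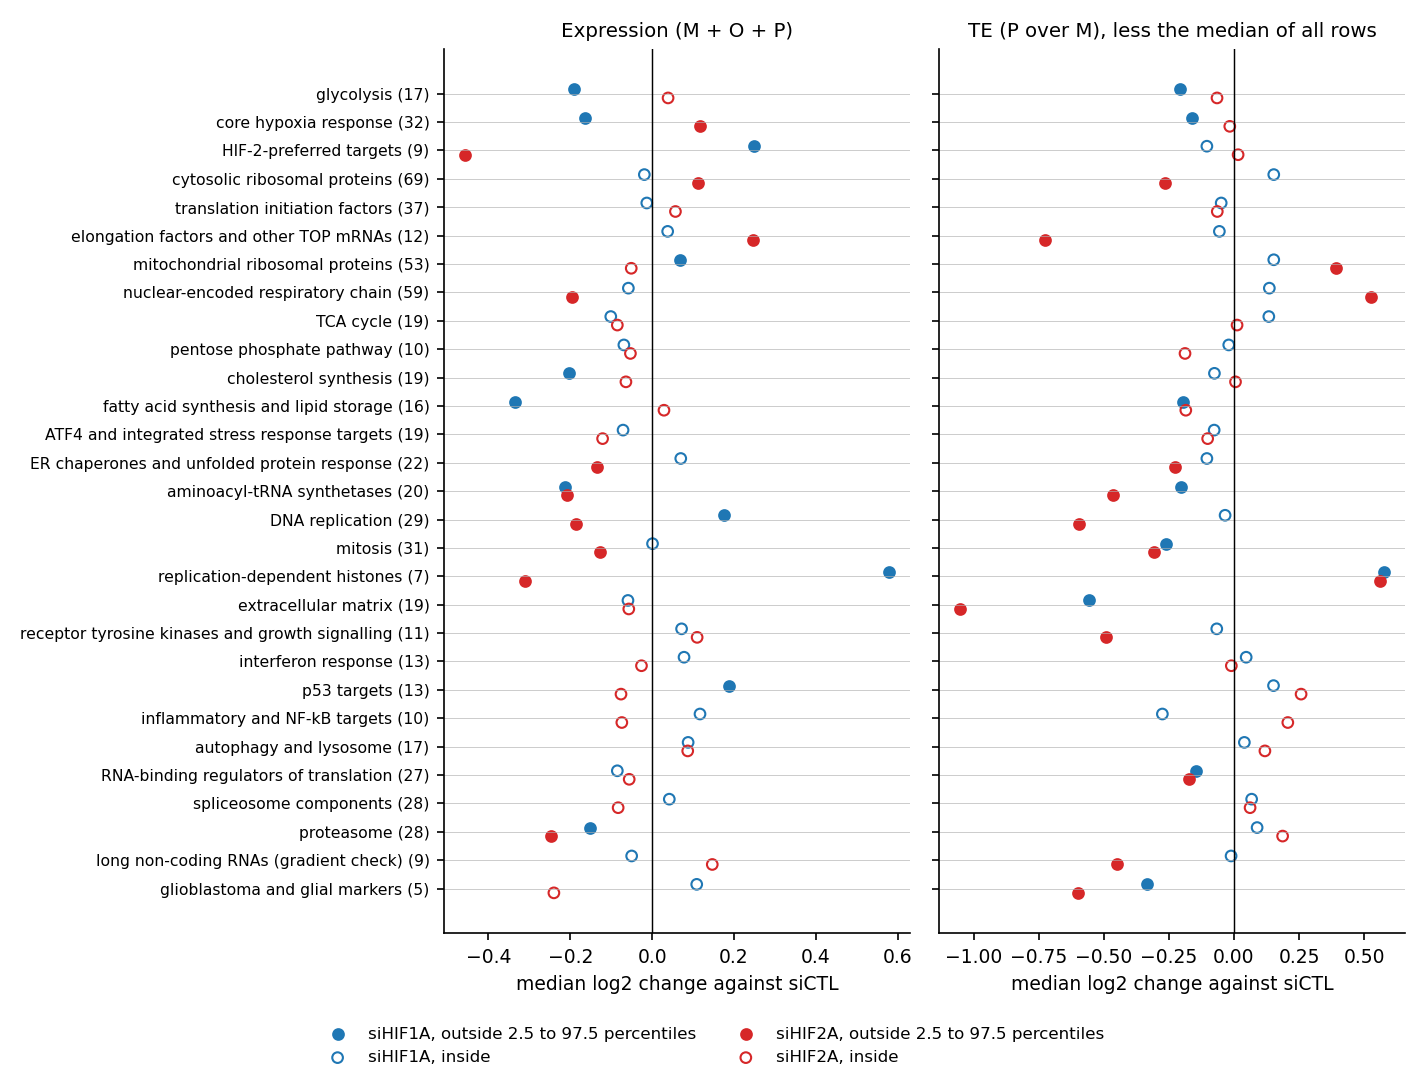
Median expression and TE change of each gene list for siHIF1A and siHIF2A, each against siCTL. TE is given relative to the median of all loci. Filled points lie outside the range of random lists matched on expression, and open points inside it. The small ribosomal protein and TE medians depend on scaling and on the place given to O, as the text states for each.

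After siHIF1A, TE of single genes such as FLNA and EIF4G1 fell more than 2-fold, and matrix genes were lower, though inside the range for their coding length. The TE median of all loci moved by 0.12 with siHIF1A and by 0.14 with siHIF2A, so TE changes are given relative to that shift. The 2-fold rule used values before subtraction: 68 loci rose and 104 fell, and after subtraction 43 rose and 167 fell. The balance turned with O added to M (48 and 34), with the length trend of coding loci removed (44 and 33) and at 1.5-fold (709 and 506). FLNA (chromosome X, 154348524 to 154374638), the actin crosslinker filamin A, fell by 2.07. Its M value went from 11.92 to 38.83 FPKM and its P value from 893.76 to 711.41. The transcriptional repressor CIC (−2.00), the microtubule protein MAP1A (−1.73) and the nuclear RNA-processing proteins PNN (−1.62), SAFB (−1.56), BCLAF1 (−1.44), SRRM2 (−1.36) and THOC2 (−1.34) followed. EIF4G1, the scaffold of the cap-binding complex, fell by 1.55, and the locus of EIF3A by 1.21. NFIC (−1.49), CABIN1 (−1.45), the HSP90B1 locus (−1.47), FASN (−1.26) and EFTUD2 (−1.14) also fell. The nuclear RNA MALAT1, which is not translated, fell by 1.34, but with O added to M its change before subtraction was 0.42, against 0.15 for all loci.

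TE rose at fewer named genes: the scaffold MPP6 (1.77), the mitochondrial protein OXLD1 (1.07), GADL1 (1.06), the glycosyltransferase POMGNT1 (1.01), GNPDA1 (1.00), CD82 (0.99), MRPL1 (0.99) and FAM195A (0.92). GABRB1 (1.40) and the signal recognition RNA copy RN7SL2 (1.60) rose as well. The HIF1A locus fell by 1.19 in TE. EIF5B, the factor reported to replace eIF2 in hypoxic initiation, stood at −1.05 but missed the rule before subtraction. EIF4E2, the hypoxic cap-binding protein, stood at −0.24.

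Extracellular matrix genes had a TE median of −0.56 below the shift (percentile below 0.01, but 3.27, inside the range, among lists also matched on coding length). Core hypoxia targets (−0.16, percentile 0.03) and glycolysis genes (−0.21, percentile 0.10) were lower too, but with O counted as translated they lay inside the range (percentiles 5.53 and 5.25), and glycolysis also did with coding length matched (2.66). CA9 stood at −0.66 and BNIP3 at −0.35. Fatty acid genes (−0.20, percentile 1.37), tRNA synthetases (−0.20, 0.76), mitosis genes (−0.26, 0.01), RNA-binding regulators (−0.14, 0.50) and glial markers (−0.34, 2.10) were also low, and histones high (0.58, percentile 100). Each of these 6 calls was lost under an alternative. With coding length matched the synthetases moved to percentile 24.17, glial markers to 23.44, fatty acids to 5.67 and RNA-binding regulators to 2.89. With O counted as translated the percentiles were 4.30 for synthetases, 5.23 for fatty acids, 2.98 for mitosis, 28.07 for RNA-binding regulators, 9.08 for glial markers and 92.6 for histones. Cytosolic ribosomal proteins stood at 0.15 (percentile 97.40), but with O counted as translated the median was −0.26, so their direction rests on that choice.

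Inside the range of random lists for TE were initiation factors (−0.05), other TOP genes (−0.06), mitochondrial ribosomal proteins (0.15), respiratory chain (0.14), tricarboxylic acid cycle (0.13), pentose phosphate pathway (−0.02), cholesterol (−0.08), ATF4 targets (−0.08), endoplasmic reticulum stress (−0.10), DNA replication (−0.03) and receptor tyrosine kinases (−0.07). So were interferon response (0.05), p53 targets (0.15), NF-κB targets (−0.28), autophagy (0.04), spliceosome (0.07), proteasome (0.09), long non-coding RNAs (−0.01) and genes preferring HIF-2α (−0.10). Some of these lists lay near an edge. NF-κB targets went from percentile 2.65 to 1.41 with coding length matched and 1.06 with transcript length matched, and stress genes from 2.71 to 1.72 at a pseudocount of 0.1 and 2.4 with a filter of 5 FPKM. From loci of a single name, initiation factors went from 4.09 to 1.72 and mitochondrial ribosomal proteins from 96.58 to 99.48.

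With siHIF2A, genes known to prefer HIF-2α were lower, together with cell-cycle and respiratory chain mRNAs, while core hypoxia targets were not. By the 2-fold rule 24 loci rose and 10 fell, 9 and 5 of them coding, with EPAS1 among the latter. Loci listed at 0 account for 4 of the 10 falls, as leaving them out gave 24 and 6. Without M the split was 29 and 20, and without P it was 26 and 35. HMOX1 (chromosome 22, 35380361 to 35394214), the heme oxygenase induced by oxidative stress, rose by 1.10, from 9.16, 14.50 and 21.25 FPKM to 18.32, 24.94 and 54.49. MT1M, a metallothionein under metal and stress control, rose by 1.24. The reductase DHRS13 rose by 1.04, FHIT by 1.13 and the pseudogene ATP5EP2 by 1.51. MAGI2 rose by 3.30, from 1.25 to 33.30 FPKM in M. C9orf84 is listed at 0 in siHIF2A P. AARS had a total change of −1.31 but rose slightly in M, so it missed the rule.

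The 9 genes known to prefer HIF-2α had a median of −0.46, at percentile 0 of the random lists, with 7 lower. Of them CCND1 (−0.69), the cyclin D1 gene, the amino acid transporter SLC7A5 (−0.65), ITPR1 (−0.77) and IGFBP3 (−0.46) led, and TGFA stood at −0.22. EGFR (−0.48), VEGFA (−0.46), NDRG1 (−0.30) and the SLC2A1 locus (−0.28) were also lower. By contrast core hypoxia targets had a median of 0.12 (percentile 99.86), which fell to 0.01 (percentile 86.79) after rescaling to the same total. EGLN1 (0.51), TMEM45A (0.49) and BNIP3 (0.46) were higher, while LDHA had −0.16, PGK1 0.06, PDK1 0.01, CA9 0.12, ANKRD37 0.09, ADM −0.04 and the PDGFRA locus −0.09.

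Summed over fractions, replication, mitosis and respiratory chain genes were lower, but not in each fraction. The M medians of replication (0.17) and mitosis (0.12) were higher, as was the P median of the respiratory chain (0.30), and rescaling took these to 0.03, −0.02 and −0.05. DNA replication had a median of −0.19 (percentile 0.02, 24 of 29 lower), with MCM4 at −0.67, MCM3 at −0.57 and PCNA at −0.47. Mitosis genes had −0.13 (percentile 0.56), with UBE2C at −0.38. The respiratory chain stood at −0.20 (percentile 0, 50 of 59 lower), led by COX6C (−0.67), NDUFA3 (−0.61) and NDUFA12 (−0.52). All 28 proteasome genes were lower (median −0.25, percentile 0), as were tRNA synthetases (−0.21, 0.08; WARS −0.71), histones (−0.31, 0.14) and endoplasmic reticulum stress genes (−0.13, 2.46; MANF −0.54, HSPA5 −0.41). Histones moved to percentile 50.47 after rescaling, and the stress genes moved inside the range under a pseudocount of 0.1, a filter of 5 FPKM and single-name members.

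Cytosolic ribosomal proteins had a median of 0.11 (percentile 100, 54 of 69 higher), which fell to 0.02 (percentile 89.12) after rescaling. The 12 other TOP genes had 0.25 (percentile 99.99, 11 higher), with NPM1 at 0.44, EEF1A1 at 0.41 and NAP1L1 at 0.39. Their medians were 0.60 in M, 0.09 in O and 0.04 in P, and 0.43, 0.385 and −0.321 after rescaling. M enters both measures, so this rise and the lower TE of the list are not separate results. VIM, a member of this list and 1 of the 5 glial markers, is listed at 0 in siHIF2A O. The glial expression medians with siHIF2A, which include it, are therefore not read as a fall. Inside the range were glycolysis (0.04), initiation factors (0.06), mitochondrial ribosomal proteins (−0.05), the tricarboxylic acid cycle (−0.09), pentose phosphate pathway (−0.05; TKT 0.72), cholesterol (−0.06), fatty acids (0.03), ATF4 targets (−0.12) and extracellular matrix (−0.06). So were receptor tyrosine kinases (0.11), interferon response (−0.03), p53 targets (−0.08), NF-κB targets (−0.07), autophagy (0.09), RNA-binding regulators (−0.06), spliceosome (−0.08), long non-coding RNAs (0.15) and glial markers (−0.24). Rescaling turned glycolysis, fatty acids, initiation factors and receptor tyrosine kinases negative and took 7 lists outside the range: extracellular matrix (−0.30, percentile 0.01), glial markers (−0.50, 0.17), RNA-binding regulators (−0.21, 0.23), the tricarboxylic acid cycle (−0.26, 0.75), spliceosome (−0.18, 1.20), ATF4 targets (−0.21, 2.10) and long non-coding RNAs (0.18, 98.96).

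After siHIF2A, TE was lower for extracellular matrix, replication and ribosomal protein genes. It was higher for the respiratory chain and the mitochondrial ribosome, though not beyond other genes of their coding length. TE rose at 449 loci and fell at 191, but after subtraction of the shift the split was 240 and 314, so the balance between both directions depends on scaling. COX6C (chromosome 8, 99873200 to 99894062), a subunit of cytochrome oxidase, rose by 1.80 as M fell from 1063.19 to 486.13 FPKM and P went from 61.30 to 108.08. CHCHD1 (1.84), MRPS14 (1.76), MRPL13 (1.41), MRPL27 (1.40) and MRPL35 (1.23) belong to the mitochondrial ribosome. COX5B (1.54), COX7A2 (1.43), SDHC (1.58) and the ATP synthase inhibitor ATPIF1 (1.58) belong to oxidative phosphorylation. The histone variant H2AFZ (1.5), GGH (1.48), S100A11 (1.42), FAM162A (1.27), MANF (1.27), IFI6 (1.17), FABP3 (1.08) and the glycolytic enzyme TPI1 (1.07) also rose.

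FLNA (−2.36), CIC (−2.14), MAP1A (−1.86) and EIF4G1 (−1.53) fell as with siHIF1A. Matrix and cell-surface genes fell too: the proteoglycan CSPG4 (−1.75), laminin LAMB2 (−1.61), tenascin TNC (−1.57), COL6A3 (−1.47) and COL6A1 (−1.28). MGLL (−1.93), AARS (−1.86), GRN (−1.66), the chaperone HSPA5 (−1.5), CENPF (−1.46), MCM5 (−1.36), PRPF6 (−1.34), PSMD2 (−1.30), LIG1 (−1.23) and EPRS (−1.18) followed. Among initiation factors the EIF3A locus (−1.54), EIF5B (−1.35) and EIF3M (−1.26) fell. EPAS1 fell by 1.37 in TE and MALAT1 by 1.93. With O added to M instead, GRN changed sign relative to the shift. CIC, COL6A1, HSPA5, PRPF6, EIF5B and MALAT1 stayed below the all-loci median of 0.21, though above 0 before subtraction.

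The respiratory chain had a TE median 0.53 above the shift (percentile 99.96), with 16 members past the 2-fold rule, but sat at percentile 83.20 among lists matched on coding length. Mitochondrial ribosomal proteins behaved alike (0.39, percentile 99.77, then 65.80). Extracellular matrix genes stood at −1.05 (percentile 0, then 0.03), with 8 past the rule. DNA replication (−0.59, percentile 0 under both; MCM3 −1.02, MCM7 −1.01) and other TOP genes (−0.73, percentile 0, then 0.01; NAP1L1 −1.10) were low whatever the match. Cytosolic ribosomal proteins stood at −0.27 (percentile 0 under both), with the RPL3 locus at −1.03 and RPS24 at −0.91. Receptor tyrosine kinases (−0.49, percentile 0.60; MET −0.93, EGFR −0.92) moved to 29.95 with length matched. tRNA synthetases (−0.46, 0.04), endoplasmic reticulum stress genes (−0.23, 1.26), mitosis (−0.31, 0.22), RNA-binding regulators (−0.17, 1.52), long non-coding RNAs (−0.45, 1.25) and glial markers (−0.60, 1.14) were low, and histones high (0.56, 99.94). With coding length matched, the synthetases moved to 4.48, stress genes to 5.74, mitosis to 11.18, RNA-binding regulators to 11.84, glial markers to 14.09 and histones to 94.02. With O counted as translated, the long non-coding RNA median before subtraction was 0.08, and after rescaling its percentile was 5.22.

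Inside the range for TE were core hypoxia targets (−0.02), glycolysis (−0.07), genes preferring HIF-2α (0.02), initiation factors (−0.06), the tricarboxylic acid cycle (0.01), pentose phosphate pathway (−0.19), cholesterol (0.01), fatty acids (−0.19), ATF4 targets (−0.10) and interferon response (−0.01). So were p53 targets (0.26), NF-κB targets (0.21), autophagy (0.12), spliceosome (0.06) and proteasome (0.19). With a filter of 5 FPKM, initiation factors went from percentile 5.6 to 2.27 and fatty acids from 7.08 to 0.95. With O counted as translated, initiation factors had −0.13 before subtraction (percentile 1.08). Of single targets VEGFA stood at 0.15, LDHA 0.25, ANKRD37 0.83, ADM 0.39, PDK1 0.24, CCND1 −0.62 and the SLC2A1 locus −0.65.

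Set directly against siHIF1A, siHIF2A gave a higher expression median for core hypoxia targets and a lower one for genes preferring HIF-2α. Of the 32 core targets 9 went the other way, as did 1 of the 9 genes preferring HIF-2α. Expression was higher at 49 loci and lower at 34, with 36 and 25 coding; rescaling gave 43 and 50. Lower with siHIF2A were coagulation factor F3 (−1.25; chromosome 1, 94529225 to 94541800), galectin LGALS3 (−1.26), the BMP antagonist GREM1 (−1.21), PTHLH (−1.16), SMAD3 (−1.08), CADM1 (−1.29), TREM1 (−1.47), DFNA5 (−1.09), CSTB (−1.01), CCND1 (−1.0) and SPINK1 (−1.63). Higher were IKBKAP (1.70), GPR146 (1.52), DHRS13 (1.45), the glyoxalase HAGH (1.42), FABP3 (1.42), DPYSL4 (1.38), AKR1B1 (1.32), TSPAN15 (1.32), RRAD (1.29), NDP (1.26) and ANKZF1 (1.15). TDRD9 is listed at 0 in siHIF1A P and DNMT3A at 0 in siHIF2A P, so neither is given a size.

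Core hypoxia targets stood at 0.25 (percentile 100, 23 of 32 higher) and glycolysis at 0.19 (99.90), with the SLC16A3 locus at 0.82, PFKFB3 at 0.54, CA9 at 0.52 and ENO1 at 0.50. Genes preferring HIF-2α stood at −0.54 (percentile 0, 8 of 9 lower). ANKZF1 (1.15) was the only core target past the 2-fold rule; LOX stood at −0.99 and EGLN1 at 0.90. Fatty acids (0.23, 99.99; FASN 0.71, SCD 0.62), cholesterol (0.20, 99.92), other TOP genes (0.23, 99.92), cytosolic ribosomal proteins (0.14, 100) and long non-coding RNAs (0.28, 99.71) were higher. Rescaling took the ribosomal protein median to 0.01, the TOP median to 0.03 and the long non-coding RNA median to 0.04. DNA replication (−0.27, 0; PCNA −0.63), mitosis (−0.12, 1.16, or 2.80 with a filter of 5 FPKM; UBE2C −0.79), mitochondrial ribosomal proteins (−0.15, 0), respiratory chain (−0.15, 0.01), ATF4 targets (−0.20, 0.17), endoplasmic reticulum stress (−0.18, 0.16; MANF −0.75), spliceosome (−0.12, 1.10) and histones (−0.44, 0.04) were lower.

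TE was higher at 128 loci and lower at 78, or 107 and 89 after subtraction of the shift. FABP3 (1.43), FAM162A (1.41), ATPIF1 (1.27), S100A11 (1.26), HSBP1 (1.24), COX5B (1.24), TM2D1 (1.21), SRP14 (1.18), B2M (1.16), MRPS14 (1.14), MRPL35 (1.12) and COX6C (1.10) were higher. MPP6 (−1.43), PLEKHG2 (−1.39), integrin ITGA5 (−1.18), NUP88 (−1.16), COL5A1 (−1.15), EPAS1 (−1.13), FDXR (−1.10) and MGLL (−1.10) were lower. Respiratory chain (0.37, percentile 99.99; 93.88 with length matched) and mitochondrial ribosome (0.26, 99.88; 83.50) were high. Cytosolic ribosomal proteins (−0.49, 0), other TOP genes (−0.45, 0.10), DNA replication (−0.48, 0), tRNA synthetases (−0.31, 0.01), receptor tyrosine kinases (−0.39, 0.21), extracellular matrix (−0.28, 0.14), mitosis (−0.18, 0.76), initiation factors (−0.11, 1.69) and long non-coding RNAs (−0.30, 1.86) were low. With coding length matched, matrix moved to 14.82 and mitosis to 7.12. The same match took 2 lists outside the range: core hypoxia targets (0.215, from 92.02 to 98.95) and histones (−0.202, from 16.59 to 1.53). The histone median before subtraction was 0.425 (percentile 99.9) with O counted as translated. At a pseudocount of 0.1 initiation factors moved to 2.57 and long non-coding RNAs to 4.69, the latter to 2.89 with O counted as translated. Under that count the ribosomal protein median before subtraction was 0.004, against 0.025 for all loci (percentile 0.10).

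Some loci changed with both siRNAs. For expression 3 loci rose and 2 fell with both siRNAs, against 0.05 and 0.02 expected of independent lists, and none moved in opposite ways. For TE 27 rose and 53 fell with both, against 2.95 and 1.92, and 2 moved in opposite ways. Part of the excess may come from the shared siCTL libraries; with 1 library per fraction the control could not be split. In 20 simulations that treated all spread as noise and shared only the control, changes with both siRNAs correlated at 0.50 for expression and TE. The observed values were 0.44 and 0.56. A value near 0.50 follows from equal noise and a shared control, so the comparison decides nothing. The noise was set from the spread across the 3 cultures, which includes any siRNA effect. These simulations made 24.3 expression calls per siRNA on average, fewer than the 41 and 34 observed. Their TE calls averaged 685.6 and 692.4, more than the 172 and 640 observed. The simulated cultures shared 3.0 expression calls on average and at most 7, against 5 observed. A shared control with all spread as noise could therefore give as many. Shared TE counts were not compared with these simulations, because the numbers of TE calls were so unlike. With counting error alone, simulated cultures shared 0.0 expression and 0.6 TE calls on average, against 5 and 80 observed. That setting leaves out all spread between cultures. The share owed to the control is not settled. Expression and TE changes had Pearson correlations of −0.21, −0.19 and −0.17 in the 3 comparisons and −0.08, −0.09 and −0.07 among coding loci. Rank correlations among coding loci were 0.01, −0.13 and −0.07. M and P enter both measures, so these values are not read as an effect on the cell.

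TE change followed coding length in every comparison. The rank correlation was −0.45 with siHIF1A, −0.58 with siHIF2A and −0.36 between them, while GC content gave 0.03, −0.04 and −0.09. In the 10% of coding genes with the shortest reading frames (median 384 bases) the siHIF2A TE change was 0.49 above the shift, and 140 genes passed the 2-fold rule upward. In the longest 10% (median 4668 bases) it was −0.51, with 70 past the rule downward. With siHIF2A the M fraction rose with length (0.44) as P fell (−0.45), and with siHIF1A mainly P fell (−0.40, against 0.18 for M).

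**Figure D3:**
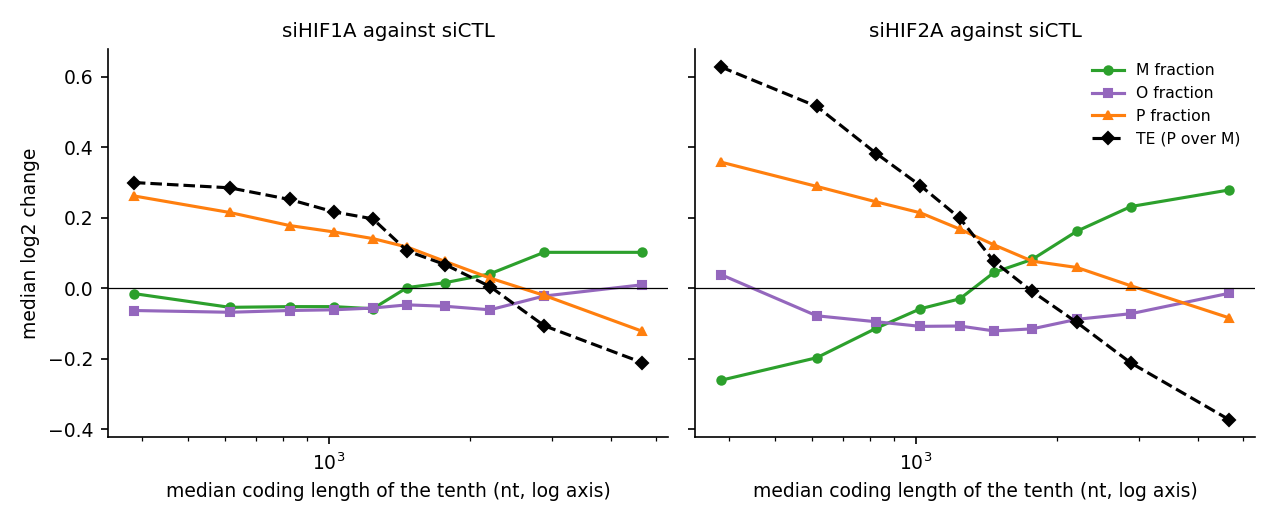
Change of the M, O and P fractions and of TE against coding length, for siHIF1A and siHIF2A against siCTL. TE is given before subtraction of the median of all loci. Lines give the median of 10 equal groups of coding genes.

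**Figure D4:**
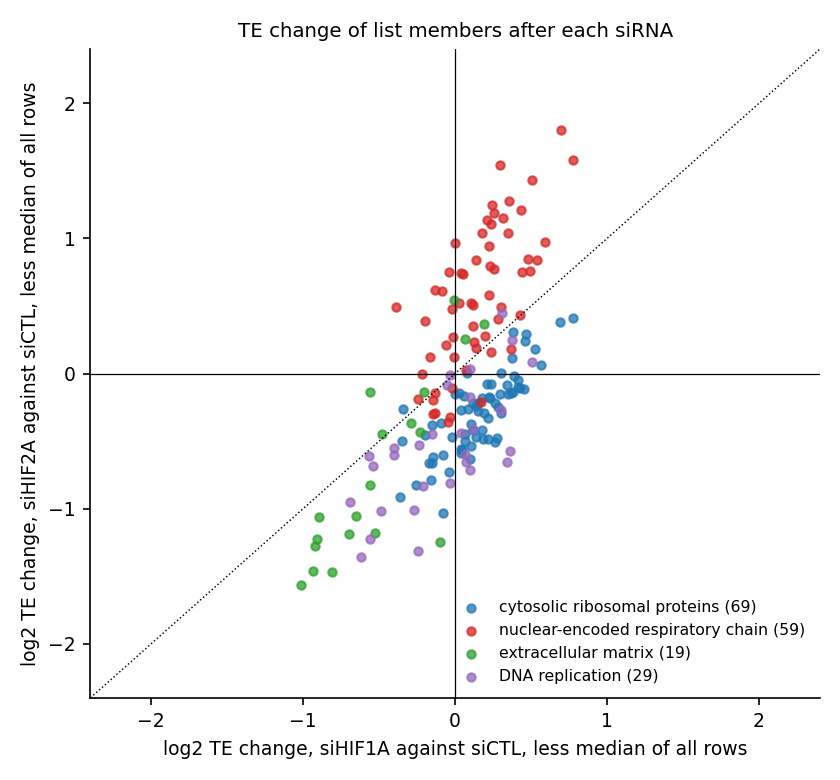
TE change of members of the cytosolic ribosomal protein, respiratory chain, extracellular matrix and DNA replication lists, relative to the median of all loci. The horizontal axis gives siHIF1A and the vertical axis siHIF2A, each against siCTL. NDUFS1 is left out. The ribosomal protein direction with siHIF1A changes when O is counted as translated.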

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

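The tests of the largest possible carry-over share, of O over M, of calls listed at 0, of coding length and of the control gradient were chosen only after the result was seen. The other tests were written before.

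PVT1, a long non-coding RNA next to MYC that shares its locus with MIR1204, moved in opposite ways with the 2 siRNAs. Its TE change was 2.786 with siHIF1A and −1.422 with siHIF2A, before subtraction of the median shift. In M, O and P it read 88.97, 22.89 and 15.83 FPKM with siCTL, 14.51, 12.94 and 19.00 with siHIF1A, and 52.31, 14.77 and 2.72 with siHIF2A. The difference between the siRNAs was not tested.

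NDUFS1, the largest subunit of respiratory complex I, has values that differ widely between libraries. It read 208.82 FPKM in M, 0.0 in O and 39.95 in P with siCTL. With siHIF1A it read 37846.3, 0.0 and 0.0, and with siHIF2A 68.93, 34.01 and 12526.3. An exact 0 can stand for a failed estimate, so these values are not read as movement along the gradient and no fold is given, and the difference between siRNAs was not tested. Loci with no gene name hold 20% of all FPKM in siHIF2A M, above the 16.1% at most in the siCTL libraries.

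Long coding sequences went with lower TE after siHIF2A. A shifted boundary between the collected fractions stays open. In the longest 10% of genes the gain in M correlated at 0.494 with P over M, a value set beforehand as evidence against it. That reasoning was wrong, because M taking in more of O would gain most where O over M is high, which correlated with P over M at 0.809. Carry-over of polysomal RNA into M stays open too. Taking an estimated share of P off M left a median of −1.192 among the 144 coding loci that fell, a value set beforehand as evidence against it. That test does not count, because the share of 3.16% assumed for siCTL exceeded all of M in 40 of those loci. With the largest share any locus allows, 3.29% off siHIF2A alone, the median was −0.935 and 56 loci were still 2-fold lower, so carry-over may account for part of the pattern.

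An effect of HIF-2α loss on the translation of long mRNAs remains a hypothesis for the same pattern. With 1.0 library per siRNA and fraction it cannot be told apart from a difference between gradients, and it could be examined only with repeated gradients.

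Respiratory chain mRNAs had higher TE and ribosomal protein mRNAs lower TE after siHIF2A. Coding length may explain the respiratory chain, whose median lies at percentile 83.2 among lists matched on coding length. For ribosomal proteins the median was −0.27 relative to the shift, at percentile 0.0 of such lists. The shortest reading frames moved up (0.49), so the length trend of coding genes has the other direction. But the match used only 5 bins of expression and 8 of coding length. With siCTL, ribosomal proteins had a median TE of −5.07, against −2.17 for the shortest reading frames. The matched lists may therefore differ from them in gradient position, and the match does not exclude coding length. An error in the control gradient alone would leave no shift against siHIF1A, where the ribosomal protein median was again at percentile 0.0. But the siHIF1A gradient could give that shift as well, and percentiles do not measure the spread between gradients. With O counted as translated the median against siHIF1A was 0.004, against 0.025 for all loci. A control error is therefore not excluded. Whether HIF-2α loss lowers ribosomal protein translation was not tested, and the siHIF2A gradient itself remains an open source.

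TE changes of 4-fold or more gathered at loci with short or embedded RNAs. Of 37 such loci, 86.5% lack a single coding name or hold a small RNA gene, against 48.6% of all loci, a ratio of 1.78. Reads of short RNAs inside the locus are therefore a candidate source for many of them, among them TIAM1, LATS1 and GABRB1. The 38 calls at these loci that have a counting error had a median change of 27.6 such errors, set beforehand as evidence against counting error. But that error takes reads as spread over a representative transcript. It may be too small where reads come from a short RNA inside the locus, so counting error is not excluded there. Counting error also stays open for the 20 calls with a library listed at 0, which overlap with those 38. In them the other culture had a median of only 5.9 FPKM in the same fraction. No biological explanation was tested for these loci.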

How the results depend on the processing

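The tests on coding loci, on coding loci without a small RNA gene, on length and on single-name members were chosen only after the result was seen. The rule gave 41, 34 and 83 expression changes for siHIF1A, siHIF2A and siHIF2A against siHIF1A, and 172, 640 and 206 TE changes. A pseudocount of 0.1 gave 72 expression changes for siHIF1A, TE counts of 560, 1357 and 543, and shared changes of 9 for expression and 282 for TE. A filter of 5 FPKM, which tests fewer loci, gave 23, 15 and 49 expression changes. The mean of the 3 log2 differences gave 21, 17 and 42. Dropping the same-sign rule gave 64 for siHIF1A and 67 for siHIF2A, and a 1.5-fold size gave 363, 282 and 442 for expression and 1215, 2819 and 1399 for TE, both by construction. Leaving out P gave 61 expression changes for siHIF2A. Coding loci alone, a smaller set, gave 24 and 14 expression changes for siHIF1A and siHIF2A, 106 TE changes for siHIF1A and 118 between siRNAs, and correlations of expression with TE of −0.082, −0.09 and −0.069. Coding loci without a small RNA gene gave 19, 7 and 48 for expression, 56, 328 and 80 for TE, and 1 and 24 shared. Removing the length trend among coding loci gave 77, 226 and 80 TE changes. P and O over M gave 374 for siHIF2A, turned the ribosomal protein TE median to −0.259 after siHIF1A and 0.004 between siRNAs, that of initiation factors after siHIF2A to −0.129, of histones between siRNAs to 0.425 and of long non-coding RNAs after siHIF2A to 0.08, all before subtraction. Rescaling, added for lists after the data were seen, turned the mitosis expression median after siHIF1A to −0.064. P over M and O gave 82, 233 and 81 TE changes. Before subtraction it also turned positive MALAT1 after siHIF1A (0.42) and siHIF2A (0.199), and after siHIF2A CIC (0.022), EIF5B (0.157), COL6A1 (0.018), GRN (0.6), HSPA5 (0.09), PRPF6 (0.116) and the loci of HSP90B1 (0.491) and MMP2 (0.082). The medians of all loci under this setting were 0.15 and 0.21, so relative to them only MALAT1 after siHIF1A, GRN and the HSP90B1 locus changed sign. Apart from smaller sets and looser rules, the cause was not tested.

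List medians were compared by whether they lay inside or outside the range of random lists. Setting the overall median to 0 cannot move that and kept all 174, though 18 medians changed sign. A pseudocount of 0.1 kept 168 of 174 with 3 sign changes, the filter of 5 FPKM 149 of 156 with 5, rescaling 155 of 174 with 37, and P and O over M 71 of 87 with 21. Matching on coding length kept 145 of 168, on transcript length 156 of 168, and single-name members 161 of 168. Of 950 values of named genes, 811 stayed within counting error at a pseudocount of 0.1, 716 with the median set to 0 and 322 after rescaling. Fewer did elsewhere: 163 of 494 TE values with P over M and O, and 134 of 423 with the length trend removed, while P and O over M moved 273 of 494. For expression 155, 175 and 121 of 456 did without M, O and P, and 163 with the mean of log2 differences. Before subtraction no other of these settings changed the sign of a called gene. The EPAS1 and HIF1A locus changes were −1.48 and −0.995 after rescaling. TE columns of the authors were not run, as the table used holds none. No paired analysis was possible because each siRNA and fraction has 1 library, and the 3 fractions of a culture are parts of 1 gradient rather than replicates. Depth limits TE more than expression, and at 2-fold the rule misses most planted changes.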

Other observations

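No tests were run in this part, and the values given were chosen after they were seen.

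In all 3 cultures the sequenced fractions placed gene classes far apart. FPKM totals differ between fractions (1892604 in siCTL M and 379452 in siCTL P), so the zero point of TE depends on scaling and classes are read against the median of all coding loci. Cytosolic ribosomal protein mRNAs had a median TE of −5.07 with siCTL, −4.88 with siHIF1A and −5.21 with siHIF2A, against 0.46, 0.62 and 0.67 for all coding loci. Respiratory chain mRNAs were also below that median (−1.94, −1.80 and −1.29), as were mitochondrial ribosomal proteins (−1.19, −0.82 and −0.54) and other TOP genes (−1.08, −1.20 and −1.59). At the other end stood extracellular matrix (3.27, 2.72 and 2.55) and receptor tyrosine kinases (2.60, 2.82 and 2.56). Next came endoplasmic reticulum chaperones (1.85, 1.67 and 1.53), glycolysis (1.61, 1.51 and 1.68) and genes preferring HIF-2α (1.40, 1.80 and 1.53), whose order differed between cultures. Short reading frames hold few ribosomes, and the shortest 10% of coding genes had a median of 58.27 FPKM in M and 12.32 in P with siCTL, the longest 10% 1.62 and 9.05.

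List shifts differed between fractions. Between siRNAs, 67 of 69 ribosomal protein mRNAs were higher in O (median 0.26) and 67 lower in P (−0.27) with siHIF2A, and both directions held after rescaling to equal totals (0.16 and −0.44). In M 65 were higher (0.14, and 0.02 after rescaling). With siHIF1A all 69 were lower in O (−0.38), but that median came to 0.02 after rescaling, while P was higher under both scalings (0.31 and 0.12). Proteasome mRNAs were lower in every fraction after siHIF2A (−0.37 in M, −0.42 in O and −0.10 in P), also after rescaling (−0.51, −0.14 and −0.46). Respiratory chain mRNAs after siHIF2A were lower in M under both scalings (−0.38 and −0.55, 51 of 59 lower as deposited), while their higher median in P (0.30) turned to −0.05 after rescaling. Matrix mRNAs were higher in M after siHIF2A (0.52 and 0.34, 17 of 19 higher as deposited), with −0.01 and −0.37 in P.

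DNA replication mRNAs after siHIF2A were higher in M (0.17, 19 of 29 higher), lower in O (−0.16) and lower in P (−0.26), and rescaling gave 0.03, 0.08 and −0.62. They were higher in all fractions after siHIF1A (0.16, 0.12 and 0.20 in M, O and P; 0.10, 0.45 and 0.05 after rescaling). Core hypoxia mRNAs after siHIF1A had 0.004 in M (16 of 32 higher), −0.17 in O and −0.11 in P, and −0.03, 0.22 and −0.30 after rescaling, so only P kept its direction under both scalings. Glycolysis mRNAs had −0.04, −0.24 and −0.11, and −0.07, 0.15 and −0.30 after rescaling, so M and P kept theirs and O did not. After siHIF2A the core hypoxia medians of 0.14, −0.07 and 0.31 turned to −0.03, 0.21 and −0.04.

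VIM, the vimentin gene and a member of the TOP and glial lists, read 2410.26, 7517.66 and 4150.41 FPKM with siCTL and 3443.82, 7909.65 and 4468.86 with siHIF1A. With siHIF2A it read 4213.5, then is listed at 0 in O, then 4265.19, so no expression change is given for it. The 13 mitochondrially encoded genes are not in the table used. Of markers of other cell types, CD74 read 15.9, 20.1 and 29 FPKM with siCTL, SNAP25 8.74, 5.58 and 4.89, KRT8 17.0, 4.91 and 0.783, KRT19 4.02, 1.25 and 0.648, and MAP2 0.575, 1.38 and 2.98. With siHIF2A KRT8 read 25.2, 7.28 and 1.66 and CD74 13.6, 14.6 and 37.3. Other markers of immune, epithelial, neuronal and endothelial cells share a locus or are not in the table used.

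Loci with no gene name were not part of the counts. Of 389 that passed the filter, 12 rose and 3 fell in expression with siHIF1A, 7 and 6 with siHIF2A, and 11 and 11 between siRNAs. For TE the counts were 26 and 46, 42 and 38, and 34 and 17.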
